A study of Homo sapiens with 12 samples.

How the data were processed

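The study measured total RNA by sequencing in 12 libraries from 2 Ewing sarcoma cell lines, 3 each of A4573 parental, A4573-R, TC-71 parental and TC-71-R. Per the labels' protocols, the cells were grown in RPMI medium with 10% fetal bovine serum, RNA was extracted from cultures in DMSO or YK-4-279, and libraries were made with a TruSeq RNA kit and read as paired ends of 100 bases. Whether the kit selected polyadenylated RNA or kept the strand is not given in the sources used here.

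Per the submitters' processing notes, the authors used Trimmomatic, STAR 2.4, HTSeq and edgeR with the GRCh38 genome. The deposited signal is a table of normalized values per library, which the authors scaled to 1000000 per library. The deposited columns add up to 0.94 to 1.12 M (M, 1000000), and each column divided by its own step gives whole numbers within 0.001, so the values are CPM, counts per 1000000 reads, on library sizes multiplied by a scaling factor of 0.894 to 1.06. These whole numbers were used as reads for depth and for the tests on counts. The scaling was kept in the main analysis.

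Each file has 58293 entries, of which 5 carry no gene name. These 5 hold 30.6% to 42.0% of the reads of a library, and the last of them 23.9% to 35.7%. They were left out of depth and tests, but the deposited scaling counts them in the library size. Of the 58288 named entries, 1932 share 253 symbols and were summed, which left 56609 symbols. Positions come from GENCODE release 29 on GRCh38, where 54855 symbols match a single gene. Named genes hold 44.0 to 62.1 M reads per library, and the 10 most abundant genes take 4.26% to 8.27% of them. Mitochondrially encoded genes take 2.78% (SD 0.17, n = 3) in A4573 parental, 2.58% (SD 0.18) in A4573-R, 6.95% (SD 0.58) in TC-71 parental and 6.47% (SD 1.35) in TC-71-R. At this depth the median SD between libraries of a group is 0.041 (A4573 parental), 0.068 (A4573-R), 0.040 (TC-71 parental) and 0.059 (TC-71-R) on the log2 scale.

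Genes with at least 1 CPM in at least 3 of the 12 libraries were tested, 14335 in all. Values were taken as log2(CPM + 1), so the log2 fold change of a gene with few CPM is closer to 0 than the ratio of its means. One model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances and a trend on mean expression. It gave the change in A4573-R, the change in TC-71-R, their difference and the difference between the parental lines. Adjusted p-values are Benjamini-Hochberg values over the tested genes from limma, with a threshold of 0.05. Genes past the threshold are called higher, lower, risen or fallen, and counts at a fold change of 2 or more are given beside them. Exact tests on 3 against 3 libraries cannot give a p below 0.1, so none was used. Overlaps of changed genes were tested with the 2-sided Fisher's exact test, adjusted over 8 overlaps.

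Gene lists were tested with camera from limma, with a fixed correlation between genes of 0.01, and adjusted over the 41 lists with at least 5 tested members. They cover the targets and partners of EWS-FLI1, drug transport, microtubules, RNA processing, cell division, stress, metabolism, signalling, differentiation and RNA quality. The 43 lists were written from general knowledge before the data were examined and hold 896 entries, of which 873 matched by symbol, 22 by an older symbol and 1 not at all. As alternatives, camera with a correlation estimated from the data and the rotation test fry were run. The camera p-value with an estimated correlation is given beside each list that passed.

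The genes named were chosen by a rule. It takes EWSR1, FLI1 and DHX9, then the 8 highest and 8 lowest fold changes of each resistant line among genes past the threshold with a mean of at least 5 CPM in the higher group, no overlap between libraries, and a gene symbol that is not a clone name. It adds up to 4 members past the threshold per list, the 6 genes per direction that changed most in both lines, the 5 per direction whose changes differ most, and all tested tubulins and drug transporters, of which the text gives some. The text does not name every gene chosen. Counts of genes without overlap and the share of opposite changes were computed over all tested genes.

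The pipeline was tested on simulated counts with the real gene means of A4573, the real library sizes and a single common spread per group for all genes. The simulation held 13429 genes and 200 changed genes, of which 49, 49, 50 and 48 entered the test at 1.3-fold, 1.5-fold, 2-fold and 4-fold. With limma it recovered 83.7% of the genes changed by 1.3-fold, 98.0% at 1.5-fold and 100% at 2-fold and 4-fold. Unchanged genes made up 7.4% of its calls, 8.0% with edgeR and 12.8% with DESeq2. In the simulation the groups differ in spread as the real ones do, but the genes of a group share one spread, which real genes do not. The share of changed genes is also far smaller than in the data. These rates therefore need not hold for the real comparisons. All 3 of 3 gene lists shifted by 0.5 were called and 0 of the others. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls a list whose members move together for other reasons.

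The gene counts, the named genes and the list calls were computed again with other pseudocounts, filters and scalings, with each of the 12 libraries left out in turn and with the sample number as a block. Other list tests were run for the lists. The gene counts and the named genes were also computed with other variance models and with the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0 on the whole reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.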

Results

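The data are RNA sequencing of 2 human Ewing sarcoma cell lines, A4573 and TC-71, and of a derivative of each that resists YK-4-279. Ewing sarcoma is a tumour of bone and soft tissue driven by the fusion protein EWS-FLI1, and YK-4-279 is a small molecule made to block the binding of EWS-FLI1 to RNA helicase A, the product of DHX9. The 4 groups are A4573 parental, A4573-R, TC-71 parental and TC-71-R, with 3 libraries in each. Per the labels, the parental libraries received the solvent DMSO and the resistant ones YK-4-279, at a dose written as 650 uM for A4573-R and 400 uM for TC-71-R. These doses are unusually high for this compound, so their unit is in doubt, and it is printed here as the labels give it. Resistance and exposure to the compound therefore go together in every comparison of a derivative with its parent, and none of the values below separates them.

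The libraries hold 44.0 to 62.1 M reads on named genes (M, 1000000). The group means are 52.8 M (SD 4.03, n = 3) in A4573 parental, 49.0 M (SD 3.38) in A4573-R, 52.8 M (SD 2.97) in TC-71 parental and 51.9 M (SD 9.25) in TC-71-R. Values are CPM, counts per 1000000 reads, given as mean ± SD with n = 3 in every group. As deposited, they count 5 entries with no gene name, which hold 30.6% to 42.0% of the reads, in the library size. They are therefore lower than counts per 1000000 reads on named genes would be. Brackets after a gene give its mean CPM in the parent and in the derivative and its log2 fold change. Of 56609 gene symbols, 14335 passed the filter and were tested. Within a group, any 2 libraries correlate at r of at least 0.9974 on log2(CPM + 1). The biological coefficient of variation is 2.5% in A4573 parental, 6.4% in A4573-R, 2.7% in TC-71 parental and 5.7% in TC-71-R. Between a parent and its derivative r is 0.968 to 0.971 for A4573 and 0.949 to 0.951 for TC-71, and between the 2 parental lines it is 0.830 to 0.831. The first 3 principal components carry 78.8%, 12.3% and 7.9% of the variance. The labels do not say that the 3 libraries of a group are separate cultures, so the p-values below measure only the spread between libraries, which may be technical.

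The first comparison sets TC-71 parental against A4573 parental and describes the ground on which resistance arose. TC-71 parental has less mRNA of the proliferation genes: all 24 genes of the G2/M and mitosis list are lower by 2-fold or more (adjusted p = 0.11 with an estimated correlation). By camera it also has lower tubulin, cholesterol synthesis and splicing factor mRNA, and higher mRNA of mitochondrially encoded genes, HOX genes and replication-dependent histone genes. These calls are lost with an estimated correlation, with adjusted p of 0.34 to 0.63. FLI1 is at 23.6 CPM in TC-71 parental and 37.1 CPM in A4573 parental, and DHX9 at 208 and 564 CPM. By limma, 12892 genes (89.9%) differ, 6576 higher and 6316 lower in TC-71, and 4386 of them by 2-fold or more. Among the gene lists, camera places G2/M and mitosis genes lower in TC-71 (0 higher, 24 lower, 0 not passed, adjusted p = 5e-10, 0.11 with an estimated correlation). S phase and E2F targets are lower as well (1 higher, 22 lower, 1 not passed, adjusted p = 1.7e-05, 0.46 with an estimated correlation). So are cholesterol synthesis genes (1 higher, 20 lower, 0 not passed, adjusted p = 4.4e-05, 0.42 with an estimated correlation). Tubulins (1 higher, 14 lower, 0 not passed, adjusted p = 0.0022, 0.34 with an estimated correlation) and splicing factors and hnRNPs are lower (2 higher, 26 lower, 2 not passed, adjusted p = 0.00022, 0.39 with an estimated correlation). EWS-FLI1 repressed targets are lower too (3 higher, 11 lower, 0 not passed, adjusted p = 0.011, 0.21 with an estimated correlation). Replication-dependent histone genes are higher in TC-71 (10 higher, 0 lower, 0 not passed, adjusted p = 0.0028, 0.34 with an estimated correlation). HOX genes (16 higher, 2 lower, 1 not passed, adjusted p = 0.0092, 0.39 with an estimated correlation) and mitochondrially encoded genes are higher (12 higher, 0 lower, 1 not passed, adjusted p = 0.026, 0.63 with an estimated correlation). The ABC and other drug efflux transporters are higher (9 higher, 2 lower, 0 not passed, adjusted p = 0.03, 0.29 with an estimated correlation), as are unfolded protein and integrated stress response genes (16 higher, 4 lower, 3 not passed, adjusted p = 0.03, 0.58 with an estimated correlation). Cancer-testis antigens are higher (7 higher, 2 lower, 0 not passed, adjusted p = 0.03, 0.34 with an estimated correlation). The lists that passed as lower also include fusion partner and cofactor genes (0 higher, 6 lower, 0 not passed, adjusted p = 0.03, 0.34 with an estimated correlation) and DNA repair (4 higher, 17 lower, 3 not passed, adjusted p = 0.011, 0.39 with an estimated correlation). Muscle and fibroblast markers (1 higher, 7 lower, 0 not passed, adjusted p = 0.011, 0.21 with an estimated correlation), nuclear oxidative phosphorylation genes (4 higher, 17 lower, 4 not passed, adjusted p = 0.046, 0.63 with an estimated correlation) and the IGF axis (4 higher, 11 lower, 0 not passed, adjusted p = 0.049, 0.34 with an estimated correlation) are the others. With a mean of at least 5 CPM asked for, the calls of the drug efflux transporters (adjusted p = 0.23), the fusion partner genes (0.058), oxidative phosphorylation (0.092) and the IGF axis (0.19) are lost. Under quantile normalization those of the last 3 are lost (0.072, 0.42 and 0.072). Oxidative phosphorylation also loses its call without A4573 parental replicate 2 (0.052) or TC-71 parental replicate 1 (0.061). The IGF axis loses it without A4573 parental replicate 1, any 1 of the A4573-R libraries or TC-71-R replicate 3 (0.051 to 0.054). It also loses it with a pseudocount of 0.25 (0.051), median-of-ratios scaling (0.058) and library weights (0.054).

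The second comparison asks how A4573-R differs from A4573 parental. The resistant line has lost most of the mRNA of PEG10 and MEST, 2 imprinted genes on chromosome 7, and gained FGF19, which encodes a secreted growth factor, and CHAC1, which encodes an enzyme that degrades glutathione and is a target of the integrated stress response. FLI1, EWSR1 and DHX9 mRNA are all lower. TUBB3 and TUBA1A rose. By camera, the neural genes and the tubulins are higher as lists, while EWS-FLI1 repressed targets, muscle and fibroblast markers, TGF-beta and BMP pathway genes, RNA helicases, splicing factors and ribosome biogenesis genes are lower. These calls are lost with an estimated correlation, with adjusted p of 0.23 to 0.68.

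FLI1 (chromosome 11, 128686535 to 128813267 in GRCh38) fell from 37.1 ± 0.938 to 21.7 ± 0.934 CPM (log2 −0.75, adjusted p = 3.7e-10). EWSR1 (chromosome 22, 29268009 to 29300525) fell from 242 ± 5.35 to 205 ± 6.68 CPM (log2 −0.24, adjusted p = 8.5e-06). DHX9 (chromosome 1, 182839369 to 182887751) fell from 564 ± 3.07 to 438 ± 32.2 CPM (log2 −0.36, adjusted p = 2.1e-05). Gene counts do not separate the fusion transcript from transcripts of the unrearranged genes. The 6 fusion partner and cofactor genes as a list did not pass (1 higher, 5 lower, 0 not passed, adjusted p = 0.13).

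PEG10 (chromosome 7, 94656325 to 94669695), which encodes a retrotransposon-derived protein, fell from 192 ± 5.80 to 3.44 ± 0.303 CPM (log2 −5.45, adjusted p = 2.3e-18). MEST (chromosome 7, 130486171 to 130506465) fell from 23.6 ± 0.334 to 0.0216 ± 0.0138 CPM (log2 −4.59, adjusted p = 2.4e-18). CAPN6 (18.9 to 0.933 CPM, log2 −3.37) and OLFML1 (7.44 to 0.337 CPM, log2 −2.66) are also among the 8 lowest. So are EN2, which encodes a homeobox transcription factor (11.6 to 0.482 CPM, log2 −3.09), and VGLL3, which encodes a cofactor of TEAD transcription factors (10.0 to 0.579 CPM, log2 −2.80). The others are THBS1, which encodes the matrix protein thrombospondin 1 (12.98 to 1.04 CPM, log2 −2.78), and RAP1GAP2 (11.7 to 0.866 CPM, log2 −2.77). FGF19 (chromosome 11, 69698232 to 69704642) rose from 0.282 ± 0.124 to 18.9 ± 0.216 CPM (log2 3.96, adjusted p = 5.8e-16). CHAC1 rose from 4.63 ± 0.0904 to 63.6 ± 34.1 CPM (log2 3.40, adjusted p = 1.4e-09). Also among the 8 highest are PPP1R3A, which encodes a regulatory subunit of a glycogen-associated phosphatase (0.703 to 18.0 CPM, log2 3.48), and the chloride channel gene ANO1 (0.0462 to 9.84 CPM, log2 3.37). The others are the smooth muscle actin gene ACTG2 (0.110 to 9.60 CPM, log2 3.25), the transcription factor gene MAF (0.0735 to 9.23 CPM, log2 3.25) and CACNG4, which encodes a subunit of calcium channels (2.39 to 31.0 CPM, log2 3.24). MBD3L3 has the highest log2 fold change on log2(CPM + 1) (0.746 to 60.8 CPM, log2 5.13), though by the ratio of mean CPM ANO1, MAF and ACTG2 rose more. MBD3L3 has near-identical copies in the genome, so its value is uncertain.

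By limma on log2(CPM + 1), 10389 of 14335 genes (72.5%) changed, 5497 higher and 4892 lower. Most changes are small: 820 genes (5.7%) changed by 2-fold or more, 500 higher and 320 lower, and the median absolute log2 fold change of all tested genes is 0.25. In 10700 genes (74.6%) the libraries of the 2 groups do not overlap, where chance gives 10%.

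The 15 tubulins, the building blocks of microtubules, rose as a list (11 higher, 2 lower, 2 not passed, adjusted p = 0.018, 0.68 with an estimated correlation). TUBB3, the neuronal beta-tubulin, rose from 6.71 ± 0.345 to 43.8 ± 2.47 CPM (log2 2.54, adjusted p = 2.1e-13). TUBA1A (158 to 874 CPM, log2 2.46) and TUBB2B (22.9 to 112 CPM, log2 2.24) rose, and TUBA4A fell (56.3 to 33.5 CPM, log2 −0.74). Tubulin genes have close paralogs and pseudogenes, so the split of reads between them is uncertain. STMN1, which encodes the microtubule-destabilizing protein stathmin, rose (405 to 809 CPM, log2 1.00). Microtubule-associated proteins as a list did not pass (13 higher, 3 lower, 7 not passed, adjusted p = 0.1). Neural genes rose (12 higher, 3 lower, 4 not passed, adjusted p = 0.026, 0.68 with an estimated correlation), a call lost with a mean of at least 5 CPM asked for (adjusted p = 0.095). Among them are ENO2 (7.85 to 56.4 CPM, log2 2.70), the synaptic vesicle gene SYP (8.02 to 24.2 CPM, log2 1.48) and the adhesion gene NCAM1 (2.13 to 6.89 CPM, log2 1.33). Cholesterol synthesis genes rose (13 higher, 1 lower, 7 not passed, adjusted p = 0.043, 0.72 with an estimated correlation). They include MVD (23.8 to 64.4 CPM, log2 1.40) and FDFT1 (226 to 467 CPM, log2 1.04). Without A4573-R replicate 1 that list has an adjusted p of 0.069, and without replicate 3 of 0.078. HOX genes rose (11 higher, 1 lower, 7 not passed, adjusted p = 0.049, 0.68 with an estimated correlation). Examples are HOXB9 (2.62 to 16.0 CPM, log2 2.21) and HOXB7 (10.0 to 20.9 CPM, log2 1.00). The HOX call is lost when 1 of several libraries is left out: the adjusted p is 0.051 without A4573 parental replicate 1 or TC-71 parental replicate 1 or 2, and 0.059 without A4573-R replicate 1 or 2.

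The lists that fell as a group include EWS-FLI1 repressed targets (3 higher, 10 lower, 1 not passed, adjusted p = 0.003, 0.23 with an estimated correlation). THBS1 belongs to it, with the smooth muscle actin gene ACTA2 (14.1 to 2.26 CPM, log2 −2.21) and the TGF-beta receptor gene TGFBR2 (18.5 to 5.82 CPM, log2 −1.52). TGF-beta and BMP pathway genes fell (3 higher, 13 lower, 4 not passed, adjusted p = 0.015, 0.34 with an estimated correlation), a call lost with a mean of at least 5 CPM asked for (adjusted p = 0.060). Examples are TGFB2 (5.25 to 0.870 CPM, log2 −1.74) and TGFB3 (26.8 to 8.78 CPM, log2 −1.51). ID3 also passed (log2 fold change −2.29, adjusted p = 0.021), but its 3 A4573-R libraries are at 0.636, 27.0 and 51.1 CPM, and without A4573-R replicate 1 its log2 fold change is −0.78. Its call is lost by edgeR (−1.31), by DESeq2 (−1.30) and without A4573 parental replicate 1 (−2.25). It is also lost without the filter and in a fit of the A4573 libraries alone (both −2.29). The 8 tested muscle and fibroblast markers, which share ACTA2 with the repressed targets and 4 genes with the matrix list, fell (1 higher, 6 lower, 1 not passed, adjusted p = 0.015, 0.25 with an estimated correlation). They include THY1 (107 to 41.2 CPM, log2 −1.36) and PDGFRB (62.9 to 26.4 CPM, log2 −1.22). RNA helicases fell (0 higher, 17 lower, 7 not passed, adjusted p = 0.003, 0.68 with an estimated correlation). Among these are EIF4A1 (10.8 to 5.18 CPM, log2 −0.96) and DDX21 (338 to 185 CPM, log2 −0.87). Ribosome biogenesis and MYC targets fell (1 higher, 18 lower, 5 not passed, adjusted p = 0.003, 0.68 with an estimated correlation). Members that fell include RRS1 (41.5 to 24.2 CPM, log2 −0.76) and WDR43 (100.5 to 61.6 CPM, log2 −0.70). Splicing factors and hnRNPs fell (3 higher, 20 lower, 7 not passed, adjusted p = 0.013, 0.68 with an estimated correlation). These include SRSF6 (194 to 113 CPM, log2 −0.78) and PRPF8 (593 to 362 CPM, log2 −0.72). Adjusting over each list alone gave the same numbers of higher and lower genes for these 10 lists.

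Among the EWS-FLI1 activated targets, which as a list did not pass (10 higher, 15 lower, 6 not passed, adjusted p = 0.43), single genes changed in both directions. GLI1, which encodes a Hedgehog transcription factor, rose from 13.6 ± 0.257 to 72.9 ± 1.21 CPM (log2 2.34, adjusted p = 3.1e-15). The neuropeptide gene CCK rose from 68.0 ± 0.965 to 207 ± 3.37 CPM (log2 1.59, adjusted p = 6.4e-12). LIPI fell (28.4 to 12.4 CPM, log2 −1.14) and so did the caveolin gene CAV1 (623 to 323 CPM, log2 −0.94). The ABC and other drug efflux transporters as a list did not pass (6 higher, 1 lower, 4 not passed, adjusted p = 0.17). ABCA3 (4.83 to 10.9 CPM, log2 1.03) and ABCC10 (22.1 to 35.4 CPM, log2 0.66) rose. ABCC1 rose little (log2 fold change 0.12, adjusted p = 0.015), and its call is lost without A4573 parental replicate 2 (log2 fold change 0.11) or A4573-R replicate 1 (0.09). ABCB1, the gene of P-glycoprotein, is close to 0 in both groups (0.202 to 0 CPM). The unfolded protein and integrated stress response list did not pass (16 higher, 5 lower, 2 not passed, adjusted p = 0.13), although ATF3 (5.26 to 51.4 CPM, log2 3.00), SESN2 (13.3 to 85.5 CPM, log2 2.5) and TRIB3 (17.7 to 66.5 CPM, log2 1.72) rose. That list has an adjusted p of 0.040 without A4573-R replicate 2 and 0.048 without replicate 3. Over the list alone, 16 of its genes are higher and 6 lower. Notch pathway genes did not pass as a list (9 higher, 4 lower, 1 not passed, adjusted p = 0.18), with HES4 (7.11 to 32.5 CPM, log2 2.04) and HEYL (7.13 to 29.7 CPM, log2 1.91) higher. The G2/M and mitosis genes (15 higher, 4 lower, 5 not passed, adjusted p = 0.086) and the S phase and E2F targets (5 higher, 15 lower, 4 not passed, adjusted p = 0.1) missed the threshold. Both have an adjusted p of 0.048 without A4573-R replicate 3. Without the filter it is 0.0054 and 0.014, and for G2/M and mitosis it is 0.017 under quantile normalization.

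The other lists did not pass the threshold of camera in A4573-R. Their adjusted p-values are 0.086 for nuclear oxidative phosphorylation genes, 0.13 for replication-dependent histone genes and 0.16 for the IGF axis. They are 0.23 for autophagy and lysosome, 0.31 for cytosolic ribosomal proteins and 0.39 for hypoxia and glycolysis. NF-kB targets and chemokines also have 0.39. The value is 0.43 each for the BCL2 family, p53 targets, cancer-testis antigens and mitochondrially encoded genes. It is 0.47 for NRF2 targets and receptor tyrosine kinases, 0.61 for DNA repair and 0.71 for epithelial markers. It is 0.92 for interferon response, antigen presentation, xenobiotic metabolism, ERK pathway output, mesenchymal and matrix genes, WNT pathway targets and inhibitors, the Hedgehog pathway, and polycomb and DNA methylation. The median, the mean and the camera statistic differ in sign for EWS-FLI1 activated targets, xenobiotic metabolism, mesenchymal and matrix genes, WNT pathway targets and inhibitors, and the Hedgehog pathway. Blood cell markers and endothelial markers were not tested, with 3 and 2 members past the filter.

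The third comparison asks the same of TC-71-R against TC-71 parental. The clearest group change is a rise of cell division genes: all 24 genes of the G2/M and mitosis list rose, CCNB1, KIF20A and TOP2A among them (adjusted p = 0.054 with an estimated correlation). They rose from a low level, since all 24 are lower by 2-fold or more in TC-71 parental than in A4573 parental. The state of the cultures at harvest was not tested for this list. By camera, the lists of S phase and E2F targets, cholesterol synthesis, the interferon response, cytosolic ribosomal proteins and tubulins are higher too. These calls are lost with an estimated correlation, with adjusted p of 0.27 to 0.65, and that of the ribosomal proteins also under quantile normalization. The stress response genes TRIB3, CHAC1, SESN2 and ATF3 fell. Single genes switched between low and high levels: GRIK3, a glutamate receptor gene, and FMO1, the gene of a flavin-containing drug-metabolizing enzyme, rose, and P2RX7, the gene of an ATP-gated ion channel, fell.

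FLI1 fell from 23.6 ± 0.187 to 20.3 ± 0.921 CPM (log2 −0.21, adjusted p = 3.1e-04). EWSR1 rose from 187 ± 1.54 to 206 ± 3.57 CPM (log2 0.14, adjusted p = 0.0011), and DHX9 rose from 208 ± 2.60 to 291 ± 21.7 CPM (log2 0.48, adjusted p = 8.2e-07). The rise of EWSR1 is lost under quantile normalization, where its log2 fold change is 0.04. The 6 fusion partner and cofactor genes as a list did not pass (3 higher, 1 lower, 2 not passed, adjusted p = 0.77).

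GRIK3 (chromosome 1, 36795527 to 37034129) rose from 1.14 ± 0.168 to 89.0 ± 4.39 CPM (log2 5.39, adjusted p = 1.9e-17). FMO1 (chromosome 1, 171248471 to 171285978) rose from 0.627 ± 0.129 to 63.9 ± 2.01 CPM (log2 5.32, adjusted p = 1.2e-17). Next come PAGE1, a gene of the cancer-testis type (4.43 to 99.3 CPM, log2 4.21), RAP1GAP2 (0.327 to 20.9 CPM, log2 4.05) and the neuronal transcription factor gene NEUROD2 (1.20 to 27.9 CPM, log2 3.71). The cancer-testis gene MAGEC1 (1.96 to 33.96 CPM, log2 3.56), SGSM1 (0.0914 to 11.6 CPM, log2 3.53) and YPEL3 (4.90 to 62.1 CPM, log2 3.42) complete the 8 highest. P2RX7 (chromosome 12, 121132819 to 121188032) fell from 49.2 ± 1.52 to 0.824 ± 0.166 CPM (log2 −4.79, adjusted p = 3.0e-17). The collagen gene COL21A1 fell from 64.2 ± 0.420 to 1.51 ± 0.101 CPM (log2 −4.70, adjusted p = 1.9e-18). Also among the lowest are SPX (103 to 3.67 CPM, log2 −4.48) and INHBE, which encodes an inhibin subunit (25.5 to 0.276 CPM, log2 −4.38). KLHDC7B (22.4 to 0.172 CPM, log2 −4.32), OSTN (19.7 to 0.117 CPM, log2 −4.21) and the lysosomal membrane protein gene LAMP3 (18.9 to 0.0767 CPM, log2 −4.21) fell by nearly as much.

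By limma, 11248 genes (78.5%) changed, 5567 higher and 5681 lower, and 1482 (10.3%) changed by 2-fold or more, 648 higher and 834 lower. The median absolute log2 fold change is 0.33. In 11627 genes (81.1%) the groups do not overlap, against 10% by chance.

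G2/M and mitosis genes rose (24 higher, 0 lower, 0 not passed, adjusted p = 1.1e-12, 0.054 with an estimated correlation). The cyclin gene CCNB1 (chromosome 5, 69167010 to 69178245) rose from 21.2 ± 0.515 to 109.6 ± 1.62 CPM (log2 2.32, adjusted p = 5.8e-17). The kinesin gene KIF20A (12.3 to 60.8 CPM, log2 2.22), the topoisomerase gene TOP2A (74.5 to 251 CPM, log2 1.74), DLGAP5 (7.32 to 35.4 CPM, log2 2.13) and HMMR (7.29 to 33.8 CPM, log2 2.07) rose too. Of the 24 genes, 19 rose by 2-fold or more. S phase and E2F targets rose (20 higher, 1 lower, 3 not passed, adjusted p = 7.3e-05, 0.65 with an estimated correlation). Examples are RRM2 (7.78 to 21.5 CPM, log2 1.34) and PCNA (59.1 to 137 CPM, log2 1.19). DNA repair genes rose (19 higher, 5 lower, 0 not passed, adjusted p = 0.0064, 0.62 with an estimated correlation). TOP2A belongs to this list as well. Splicing factors and hnRNPs rose (20 higher, 4 lower, 6 not passed, adjusted p = 0.013, 0.65 with an estimated correlation). Among them are HNRNPA1 (728 to 1381 CPM, log2 0.92) and HNRNPD (195 to 358 CPM, log2 0.87). Cytosolic ribosomal proteins rose (20 higher, 3 lower, 2 not passed, adjusted p = 0.0017, 0.65 with an estimated correlation). Examples are RPS14 (315 to 814 CPM, log2 1.37) and RPL3 (1047 to 2140 CPM, log2 1.03). The calls of these last 2 lists are lost under quantile normalization, with adjusted p of 0.14 and 0.24. Ribosomal protein genes have many pseudogenes, so their values are uncertain.

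Interferon response genes rose (15 higher, 3 lower, 0 not passed, adjusted p = 0.0038, 0.27 with an estimated correlation). They include IFI6 (2.43 to 14.2 CPM, log2 2.14), IFIH1, a sensor of double-stranded RNA (5.71 to 24.8 CPM, log2 1.94), IFITM1 (15.8 to 46.6 CPM, log2 1.51) and IFITM3 (22.8 to 58.4 CPM, log2 1.32). Cholesterol synthesis genes rose (17 higher, 2 lower, 2 not passed, adjusted p = 0.0025, 0.65 with an estimated correlation). Examples are FDPS (56.0 to 131 CPM, log2 1.21) and MVK (3.20 to 7.43 CPM, log2 1.00). Nuclear oxidative phosphorylation genes rose (19 higher, 3 lower, 3 not passed, adjusted p = 0.005, 0.65 with an estimated correlation). These include NDUFA4 (66.0 to 125 CPM, log2 0.92) and ATP5C1 (81.8 to 148 CPM, log2 0.85). Over that list alone, 20 genes are higher and 3 lower. Tubulins rose (11 higher, 2 lower, 2 not passed, adjusted p = 0.005, 0.62 with an estimated correlation). Higher are TUBB4B (69.9 to 229 CPM, log2 1.69), TUBA1A (55.4 to 159 CPM, log2 1.51) and TUBB4A (26.6 to 75.2 CPM, log2 1.46). TUBA4A (2.75 to 0.560 CPM, log2 −1.26) and TUBE1 (29.6 to 12.6 CPM, log2 −1.17) fell. STMN1 rose (119.9 to 410.4 CPM, log2 1.76). TUBB did not pass (log2 fold change 0.60, adjusted p = 0.062), but its fold change passes without TC-71-R replicate 1 (0.88) or replicate 3 (0.80). Without replicate 2, the only one of the 3 far above the parent, it is 0.13. TUBB also passes by edgeR (0.82), with the sample number as a block and with library weights (both 0.60). The unfolded protein and integrated stress response list fell (2 higher, 17 lower, 4 not passed, adjusted p = 0.0025, 0.65 with an estimated correlation). Members include TRIB3 (622 to 62.8 CPM, log2 −3.29), CHAC1 (56.5 to 8.02 CPM, log2 −2.67), SESN2 (80.2 to 12.7 CPM, log2 −2.57) and ATF3 (51.8 to 11.9 CPM, log2 −2.03). Of its genes, 15 fell by 2-fold or more. For the 9 lists of this comparison other than oxidative phosphorylation, adjusting over the list alone gave the same numbers of higher and lower genes.

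EWS-FLI1 activated targets did not pass as a list (16 higher, 10 lower, 5 not passed, adjusted p = 0.49). PADI2 (33.6 to 115 CPM, log2 1.74), VRK1 (31.2 to 93.8 CPM, log2 1.55) and LIPI (11.6 to 24.2 CPM, log2 1.00) rose, and NPY1R (33.98 to 12.1 CPM, log2 −1.43), GLI1 (18.9 to 9.38 CPM, log2 −0.94) and CAV1 (427 to 305 CPM, log2 −0.49) fell. EWS-FLI1 repressed targets did not pass either (8 higher, 2 lower, 4 not passed, adjusted p = 0.26). In that list the IGF-binding protein gene IGFBP3 rose (0.567 to 7.56 CPM, log2 2.45) and TGFBR2 fell (14.3 to 7.83 CPM, log2 −0.80). The ABC and other drug efflux transporters did not pass (3 higher, 6 lower, 2 not passed, adjusted p = 0.3). ABCB1 (5.86 to 1.31 CPM, log2 −1.57), ABCC4 (59.3 to 26.6 CPM, log2 −1.13) and ABCC1 (32.4 to 27.6 CPM, log2 −0.23) fell. In that list 3 genes are higher and 7 lower when adjusted over the list alone. Cancer-testis antigens did not pass (5 higher, 2 lower, 2 not passed, adjusted p = 0.29), although PRAME (11.8 to 65.6 CPM, log2 2.37) and MAGEA12 (4.52 to 26.2 CPM, log2 2.29) rose. Outside the lists that passed, AKR1C3, an aldo-keto reductase gene of the NRF2 list (0.584 to 13.7 CPM, log2 3.21), and the matrix genes DCN (3.96 to 30.4 CPM, log2 2.66) and LUM (3.99 to 15.1 CPM, log2 1.68) rose. The matrix list, with 16 genes higher, 9 lower and 3 not passed, and the muscle and fibroblast list, with 4 higher, 1 lower and 3 not passed, did not pass.

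The remaining lists did not pass in TC-71-R. The adjusted p is 0.15 for epithelial markers, 0.19 for mesenchymal and matrix genes, 0.26 for antigen presentation and 0.3 for muscle and fibroblast markers. It is 0.75 each for hypoxia and glycolysis, WNT pathway targets and inhibitors, mitochondrially encoded genes and replication-dependent histone genes. It is 0.8 for the BCL2 family, and 0.82 for xenobiotic metabolism, ERK pathway output, NF-kB targets and chemokines, and polycomb and DNA methylation. RNA helicases have 0.87. NRF2 targets, the Notch pathway, and autophagy and lysosome have 0.92. It is 0.93 for microtubule-associated proteins, p53 targets, receptor tyrosine kinases, neural genes, the Hedgehog pathway, ribosome biogenesis and MYC targets, and HOX genes. It is 0.96 for the IGF axis and the TGF-beta and BMP pathway. The median, the mean and the camera statistic differ in sign for p53 targets, NRF2 targets, the IGF axis, receptor tyrosine kinases, the Hedgehog pathway, ribosome biogenesis and MYC targets, autophagy and lysosome, and HOX genes.

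**Figure D1:**
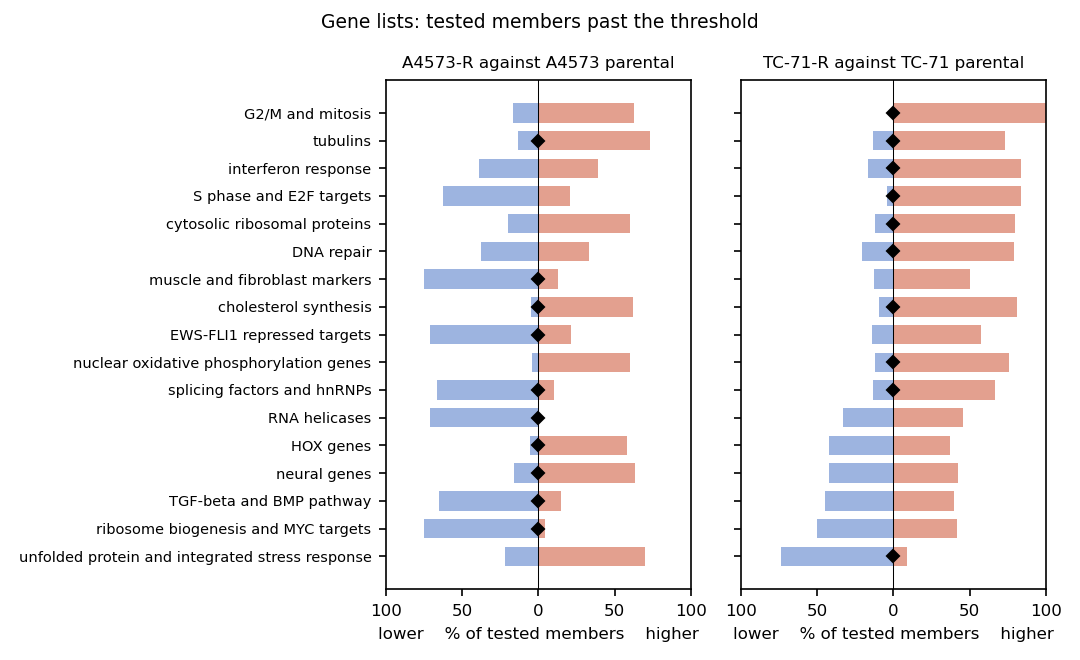
Percent of the tested members of each gene list (vertical axis) that passed the threshold lower (blue, left) or higher (red, right) in A4573-R and in TC-71-R, for the 17 lists that passed in at least 1 of them. A diamond marks a list with an adjusted p under 0.05 by camera with a fixed correlation of 0.01, 10 lists in each derivative, and all 24 G2/M and mitosis genes are higher in TC-71-R.

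The fourth comparison asks which changes the 2 derivatives share. Genes higher in both include IFI16, a sensor of foreign DNA, the transcription factor gene ETS2 and IFIH1, and genes lower in both include the collagen genes COL24A1 and COL16A1, VGLL3 and the elastic fibre gene FBLN5. STMN1 rose in both. The tubulin and cholesterol synthesis lists are higher in both by camera, though TUBA4A fell in both. These calls are lost with an estimated correlation, with adjusted p of 0.62 to 0.72, and that of cholesterol synthesis in A4573-R also without replicate 1 (0.069) or 3 (0.078). Nearly as many of the changes of 2-fold or more go in opposite directions as in the same one.

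Of the 8241 genes changed in both lines, 4482 (54.4%) changed in the same direction and 3759 in opposite directions. Of these, 2355 are higher in both and 2127 lower in both, where independent lists of these sizes give 2134.8 and 1938.7 (2-sided Fisher test, adjusted p = 8e-14 and 3.2e-11). Opposite changes are fewer than such lists give, 2046 higher in A4573-R against 2178.5 and 1713 higher in TC-71-R against 1899.8 (adjusted p = 3.7e-06 and 3.2e-11). At 2-fold or more, 188 genes changed in both, 95 in the same direction (50.5%) and 93 in opposite ones. Of these, 52 are higher in both, where independent lists give 22.6 (adjusted p = 2.9e-08). Lower in both are 43, where they give 18.6 (4.2e-07). Another 69 are higher in A4573-R and lower in TC-71-R, where they give 29.1 (3.2e-11). The reverse holds for 24, where they give 14.5 (0.014). At this fold change every combination of directions is thus more frequent than independent lists give, so the excess is not particular to shared directions. The Fisher tests count genes as independent, which genes that change together are not, so their p-values may be too small. Over all tested genes the 2 sets of log2 fold changes correlate at r = 0.035 (Pearson) and 0.065 (Spearman), where genes are not independent replicates. The comparisons share no library.

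The genes that rose most in both are IGSF21 (2.94 in A4573-R and 2.69 in TC-71-R, log2 fold changes), NGEF (2.84 and 1.95) and IFI16 (1.83 and 2.60). Next are ETS2 (1.79 and 2.4), EEF1A2, which encodes an elongation factor of translation (1.68 and 1.94), and the netrin receptor gene UNC5A (2.06 and 1.56). IFIH1 (1.48 and 1.94) rose in both as well. The genes that fell most in both are COL24A1 (−2.24 and −2.06), VGLL3 (−2.80 and −1.68), and COL16A1 (−1.68 and −3.04). Then come the potassium channel subunit gene KCNE3 (−1.61 and −1.54), FBLN5 (−1.53 and −1.64) and STAMBPL1 (−1.47 and −2.04). Each passed the threshold in both lines, with values in 3 of 3 resistant libraries on the same side of all 3 parental ones.

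**Figure D2:**
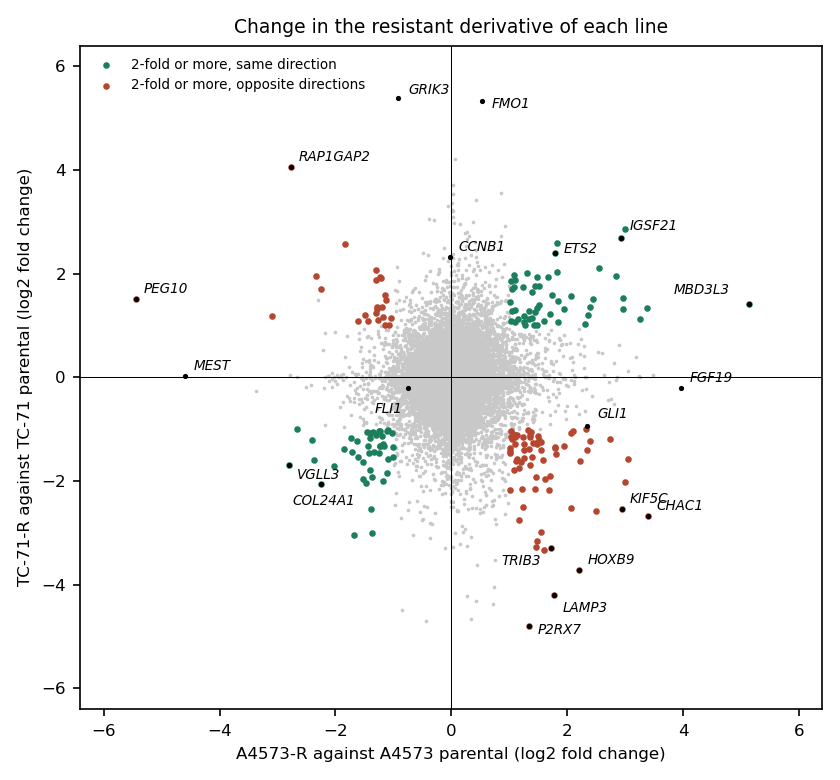
Log2 fold change of each tested gene in A4573-R (horizontal axis) and in TC-71-R (vertical axis), each against its parent with n = 3 libraries per group. Any genes of the Y chromosome, XIST and TSIX are left out. Genes past the threshold by 2-fold or more in both lines are green (95 genes, same direction) or red (93 genes, opposite directions). The labelled genes, a selection of those named in the text, are black.

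The fifth comparison tests the difference of the 2 changes itself, as TC-71 minus A4573. PEG10 fell in A4573-R and rose in TC-71-R, from 52.5 ± 0.917 to 151 ± 9.55 CPM (log2 1.5, adjusted p = 6.7e-13). RAP1GAP2 did the same. KIF5C, which encodes a neuronal kinesin, and HOXB9, a homeobox gene, rose in A4573-R and fell in TC-71-R. LAMP3, P2RX7 and CHAC1 also moved in opposite directions. IFITM3 fell in A4573-R (57.0 to 22.8 CPM, log2 −1.28) and rose in TC-71-R.

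KIF5C (chromosome 2, 148875250 to 149026759) rose in A4573-R from 1.76 ± 0.0391 to 20.2 ± 0.980 CPM (log2 2.94, adjusted p = 5.2e-16). In TC-71-R it fell from 22.03 ± 0.388 to 2.97 ± 0.110 CPM (log2 −2.54, adjusted p = 1.1e-15). HOXB9 (chromosome 17, 48621159 to 48626356) fell in TC-71-R from 62.1 ± 2.72 to 3.79 ± 0.253 CPM (log2 −3.72, adjusted p = 2.2e-13). LAMP3 (0.768 to 5.13 CPM, log2 1.78) and P2RX7 (0.827 to 3.64 CPM, log2 1.34) rose in A4573-R. FMO1 rose there less than in TC-71-R (0.151 to 0.654 CPM, log2 0.52), and GRIK3 fell (0.991 to 0.0509 CPM, log2 −0.92). MEST fell in A4573-R and lies near 0 in both TC-71 groups. By limma, 11197 genes (78.1%) differ between the lines in their change, 5439 with the higher log2 change in TC-71 and 5758 with the lower, and 2367 by 2-fold or more.

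Of the 41 lists, 10 differ between the lines by camera. G2/M and mitosis genes have the higher change in TC-71 (24 higher, 0 lower, 0 not passed, adjusted p = 6.5e-11, 0.065 with an estimated correlation). So do splicing factors and hnRNPs (24 higher, 1 lower, 5 not passed, adjusted p = 0.00014, 0.56 with an estimated correlation). S phase and E2F targets follow (19 higher, 3 lower, 2 not passed, adjusted p = 0.00025, 0.65 with an estimated correlation). EWS-FLI1 repressed targets, lower in A4573-R alone by camera, are next (11 higher, 0 lower, 3 not passed, adjusted p = 0.00045, 0.065 with an estimated correlation). DNA repair genes (18 higher, 3 lower, 3 not passed, adjusted p = 0.007, 0.56 with an estimated correlation) and interferon response genes (13 higher, 3 lower, 2 not passed, adjusted p = 0.0082, 0.19 with an estimated correlation) also have the higher change in TC-71. The same holds for muscle and fibroblast markers (7 higher, 1 lower, 0 not passed, adjusted p = 0.012, 0.19 with an estimated correlation). RNA helicases (17 higher, 2 lower, 5 not passed, adjusted p = 0.021, 0.65 with an estimated correlation) and cytosolic ribosomal proteins (17 higher, 5 lower, 3 not passed, adjusted p = 0.023, 0.67 with an estimated correlation) complete the 9. The calls of these last 2 are lost under quantile normalization, with adjusted p of 0.092 and 0.38. The unfolded protein and integrated stress response list has the lower change in TC-71 (2 higher, 16 lower, 5 not passed, adjusted p = 0.0065, 0.63 with an estimated correlation). Tubulins (7 higher, 5 lower, 3 not passed, adjusted p = 0.69) and cholesterol synthesis (10 higher, 7 lower, 4 not passed, adjusted p = 0.71) did not pass this test. Nor did HOX genes (4 higher, 9 lower, 6 not passed, adjusted p = 0.26), neural genes (5 higher, 11 lower, 3 not passed, adjusted p = 0.17) and the ABC and other drug efflux transporters (2 higher, 7 lower, 2 not passed, adjusted p = 0.09). Without the filter the neural genes (0.0092) and the drug efflux transporters (0.021) pass by camera. NF-kB targets and chemokines (0.0011) and ribosome biogenesis and MYC targets (0.0066) then pass as well.

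**Figure D3:**
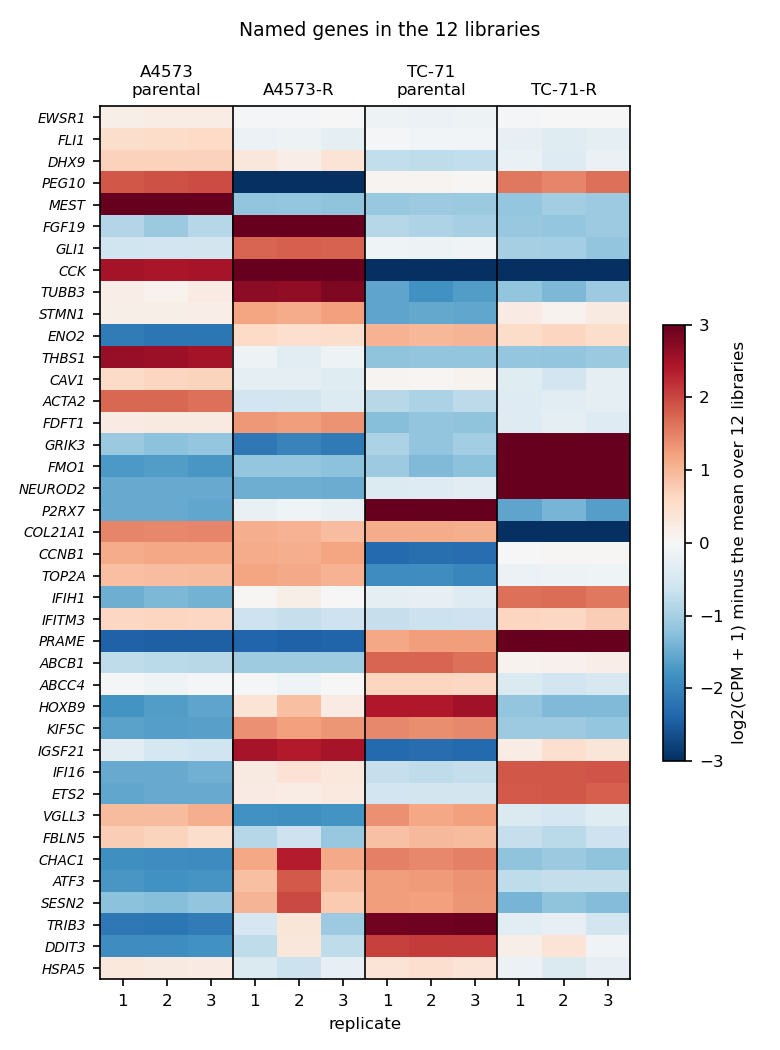
Level of 40 genes in each of the 12 libraries, as log2(CPM + 1) minus the gene's mean over the libraries, with colours held at 3 above and below that mean. Columns are the 3 libraries of each group, and the stress response genes CHAC1, ATF3, SESN2 and TRIB3 are highest in A4573-R replicate 2 among the A4573 libraries.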

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

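The tests of scaling, of library labels and of culture state below, and the splits of the libraries for the gene counts of single comparisons, were chosen after the results were seen. The splits for the difference between the lines, for shared changes and for the gene lists were planned before their values were known.

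The 2 lines differ in how their derivatives changed, by a test of the difference itself (TC-71 minus A4573, log2, limma). The difference passed the threshold in 11197 genes (78.1%). It passed in 112 of the 116 genes named with values for a comparison, most of which were chosen for a large change, so that share is no separate evidence. Among the genes chosen for it, the change is higher in TC-71 for PEG10 (6.95), RAP1GAP2 (6.82), GRIK3 (6.32), FMO1 (4.80) and MEST (4.61), and lower for P2RX7 (−6.13), CHAC1 (−6.07), LAMP3 (−5.99), HOXB9 (−5.92) and KIF5C (−5.48). EWSR1 (0.38), FLI1 (0.54) and DHX9 (0.84) also differ. The gene lists that differ, with adjusted p by camera, are G2/M and mitosis (6.5e-11), splicing factors and hnRNPs (0.00014), S phase and E2F targets (0.00025), EWS-FLI1 repressed targets (0.00045), the unfolded protein and integrated stress response (0.0065), DNA repair (0.0070), interferon response (0.0082), muscle and fibroblast markers (0.012), RNA helicases (0.021) and cytosolic ribosomal proteins (0.023). The calls of the last 2 are lost under quantile normalization (0.092 and 0.38). With an estimated correlation, 0 lists pass by camera (5 of the 41 at an unadjusted p under 0.05), and fry calls 34 of the 41.

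The libraries were also split in other ways. For the change within A4573, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes (10389, highest other 1). For TC-71 it was 1 of 10 (11248, highest other 0), and for the parental lines 1 of 10 (12892, highest other 0). For the gene lists, 1 of 10 splits in A4573 gave as many (10, highest other 8) and 3 of 10 in TC-71 (10, highest other 11), so 2 splits that mix TC-71 parental and TC-71-R gave at least as many lists as the real one. With 10 splits a share under 0.05 cannot be reached. Every split other than the real one mixes the 2 groups, so the real change between them adds to the spread within each side. Gene counts then fall near 0 whatever the cause, while part of the change stays and lists can still pass. These counts therefore do not test whether the groupings arose by chance. For the shared changes, 1 of 100 splits drawn from the 200 within the lines gave as many genes (4482, highest other 3759). The 98 drawn splits that mix parent and derivative gave 0, and 3759 comes from the split that keeps both groupings and exchanges parent and derivative in 1 line, so this count does not test whether the lines share changes. For the difference between the lines, 2 of 100 gave as many (11197, highest other 11391). The 77 splits that mix both lines gave 0, the 21 that mix 1 line gave 3203 to 6158, and 11391 comes from the same exchange, so this count does not test whether the lines differ.

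Of the 23 tested unfolded protein and integrated stress response genes, 15 passed higher in A4573-R and lower in TC-71-R, and the median difference of the 2 changes is −1.88 (log2). Scaling between libraries is argued against, with a median difference of −1.98 under quantile normalization. So is a single mislabelled library. The lowest correlation within any group is 0.9974, and the highest between the groups of a line is 0.971. An exchange of parent and derivative labels for all libraries of a line would leave these correlations unchanged, so it was not tested. The state of the cultures at harvest stays open: the list members have a median SD of 0.313 between the A4573-R libraries, above all 10000 matched gene lists, and A4573-R replicate 2 lies above the mean of the other 2 libraries in 17 of 23 genes. The median SD is 0.090 in TC-71-R, also above all matched lists, but 0.033 in A4573 parental and 0.030 in TC-71 parental, at percentiles 68.1 and 40.7 of the matched lists. A low spread does not exclude a state shared by all libraries of a group, so the parental groups are not cleared by it. By camera with the fixed correlation, the list is also higher in TC-71 parental than in A4573 parental. Differences in nutrients, density or time after feeding may therefore contribute, and resistance and exposure to YK-4-279 remain untested as causes.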

How the results depend on the processing

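The alternatives were fixed before the data were examined, with 2 exceptions chosen after seeing the data: the library weights by group, because the resistant groups spread more, and the alternatives for the lists that differ between the parents and between the changes of the 2 lines. Of 172 alternative values of the 7 counts, 162 stayed within 1.5 times of the reported count. With a fold change of at least 2 asked for as well, 820 genes changed in A4573-R, 1482 in TC-71-R, 2367 between the lines, 95 in the same direction and 4386 between the parents, which follows from the stricter threshold. Without the filter 18 lists passed in A4573-R, and the cause was not tested. With the correlation estimated, 0 lists passed by camera in A4573-R (3 at an unadjusted p under 0.05) and 0 in TC-71-R (2), while fry called 30 and 37, since it asks whether a list changed at all and not whether it changed more than other genes. By fry, 4 lists without a call passed in the direction opposite to their camera statistic: xenobiotic metabolism (0.0095) and the Hedgehog pathway (0.0018) in A4573-R, and the IGF axis (2.9e-06) and the Notch pathway (0.031) in TC-71-R. The cause was not tested.

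Leaving out 1 library at a time gave 9807 to 10632 genes in A4573-R, 10790 to 11410 in TC-71-R, 10884 to 11220 between the lines, 4193 to 4511 in the same direction, 12631 to 12989 between the parents, and 8 to 12 lists in A4573-R and 10 each time in TC-71-R. The edgeR test gave 10527, 11410, 10836, 4568 and 12927 genes in that order, DESeq2 10343, 11253, 10723, 4471 and 12817, and the library weights 10170, 11385, 11185, 4416 and 13234. Median-of-ratios scaling divided the CPM by 0.982 to 1.03, and no scaling moved the median of all genes by 0.1 or more.

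The sample numbers do not pair the libraries: the deviations of libraries with the same number in parent and derivative correlate at −0.097 to 0.016. With the number as a replicate block, 10279 genes changed in A4573-R, 11151 in TC-71-R, 11088 between the lines, 4380 in the same direction and 12195 between the parents, with 10 lists in each derivative.

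For the gene lists, 1701 of 1802 alternative values kept the side of the threshold, 34 lost the call, 63 gained one and 4 passed in the other direction. A list that passed in neither setting was counted as kept even where its direction changed. Outside fry and the estimated correlation, the calls lost are HOX genes in A4573-R (also 0.056 with a mean of at least 5 CPM, 0.066 with a pseudocount of 5 and 0.11 under quantile normalization), cholesterol synthesis there, TGF-beta and BMP pathway (0.060) and neural genes (0.095) there with a mean of at least 5 CPM, and ribosomal proteins and splicing factors in TC-71-R under quantile normalization. Gained outside fry are, in A4573-R, microtubule-associated proteins (0.045), G2/M and mitosis (0.017) and oxidative phosphorylation (0.017) under quantile normalization, fusion partner genes with a mean of at least 5 CPM (0.038), 8 lists without the filter, and the calls without 1 library given above. In TC-71-R they are cancer-testis antigens with a mean of at least 5 CPM (0.015) and, without the filter, EWS-FLI1 repressed targets (0.046), antigen presentation and mesenchymal and matrix genes (both 0.041). For the lists that differ between the parents and between the changes of the 2 lines, by camera with the fixed correlation, 17 and 2 of 819 values each lost a call, 15 and 6 gained one, and 14 to 24 and 8 to 14 lists passed. The estimated correlation, with which all of these calls are lost, and fry are not among those values. Among those gained is ribosome biogenesis for the difference of the changes without A4573-R replicate 3 (0.024), and between the parents hypoxia and glycolysis, ERK pathway output and epithelial markers without A4573 parental replicate 3 (each 0.050). For the named genes, 3669 of 3682 values kept call and direction, 8 lost the call (ID3 and ABCC1 in A4573-R, EWSR1 in TC-71-R) and 5 gained one (TUBB in TC-71-R).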

Other observations

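The chromosomes below were chosen after their medians were seen, and the 4 tests on them were written before their results.

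In TC-71-R, genes on chromosomes 13 and 15 are lower as a whole. The median log2 fold change is −0.51 over 250 tested genes on chromosome 13 and −0.43 over 454 on chromosome 15, followed by −0.30 over 775 on chromosome 12, and lies between −0.15 and 0.14 on the other chromosomes examined. The 704 genes of chromosomes 13 and 15 have a median of −0.46, and the lowest of 10000 random lists matched on mean expression −0.07. These lists treat genes as independent, and the medians of chromosomes 12 (−0.30) and 20 (−0.15) also lie below −0.07. Chromosomes 13 and 15 were chosen by the same medians. The comparison therefore argues only against independent placement of the changed genes. After a trend on GC content and transcript length was removed the median is −0.41. Of the genes with a mean of at least 5 CPM, 83.8% are lower, so the shift is not confined to a few strongly changed genes. The low medians by which these chromosomes were chosen already implied this, so that share is no separate evidence. In 3 groups by mean expression of the 507 genes with a mean of at least 5 CPM, the highest median is −0.49, so fewer copies of these chromosomes in TC-71-R, whether through resistance or through outgrowth of a subclone, may be the source, as a hypothesis on RNA alone, since DNA was not analysed here.

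In A4573-R, the median is 0.25 over 680 genes of chromosome 6, where 74.6% are higher, and between −0.19 and 0.17 on the other chromosomes examined. Windows of 20 Mb with at least 25 genes have medians of −0.66 on chromosome 10 from 40 to 60 Mb, −0.55 on chromosome 11 from 20 to 40 Mb, −0.54 on chromosome 5 from 20 to 40 Mb and −0.50 on chromosome 3 from 20 to 40 Mb. In TC-71-R the same 4 windows have medians of 0.06, 0.03, −0.11 and −0.04. In TC-71-R, outside chromosomes 12, 13 and 15, windows are lower on chromosome 8 from 100 to 120 Mb (−0.54 over 54 genes) and on chromosome 20 from 20 to 40 Mb (−0.43 over 113). These windows were not tested.

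The neighbours of PEG10 on chromosome 7, SGCE and CASD1, also fell in A4573-R, from 16.6 to 7.07 CPM and from 22.1 to 11.4 CPM. These 2 genes were chosen after their values were seen. In A4573-R the windows of chromosome 7 from 60 to 160 Mb, where PEG10 and MEST lie, have medians of −0.26 to −0.13. Those from 0 to 60 Mb have medians of 0.04 to 0.11. SGCE and CASD1 fell by more than these medians. Since they were chosen for their values and the region was not tested, their fall is still not shown to be local to PEG10.

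Some genes vary between libraries of a group far more than genes of the same level. Of the 143 genes with the most excess spread (the top 1%), 18 lie on chromosome 6 from 28 to 34 Mb, the region of the major histocompatibility complex, which holds 97 tested genes (18.6%), against 125 of 14017 genes elsewhere (0.892%). Among genes with a mean of at least 5 CPM the odds ratio is 25.5. TUBB is one of them, with 307, 195 and 196 CPM in the 3 A4573 parental libraries. The gene with the most excess spread is ID3. This was noticed in the data and no explanation was tested.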
